A study of Mus musculus with 23 samples.

How the data were processed

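The series holds polyadenylated RNA from mouse bone marrow-derived macrophages (BMDMs), which are macrophages grown from bone marrow cells, labelled wild type (WT) or Stk40 knockout (KO). Cells were untreated at the time point called T0 and exposed to lipopolysaccharide (LPS), a bacterial cell wall component, at T6, T16 and T32. The unit of time is not given in the sources used here. Per the labels' protocols, RNA was treated with DNase on the column, libraries were made with a TruSeq RNA kit (version 2) and sequenced on a HiSeq 4000 as single-end 50 bp reads. That kit does not mark strand, so reads from overlapping and antisense genes could not be told apart.

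Per the submitters' processing notes, reads were aligned with GSNAP to GRCm38. The versions, the annotation release and the counting tool are not given in the sources used here. The authors deposited raw counts per Ensembl gene and, per the file headers, size-factor-adjusted RPKM (nRPKM) for each library, both as tables of the whole series and as 1 table per library. In 23 of 23 libraries the counts and the nRPKM values were identical in both kinds of table. The nRPKM values equalled the count divided by gene size and by a single factor per library, and that factor was 0.718 to 1.684 times the one that plain RPKM would use; how the authors set it is not given in the sources used here. The deposited counts were used for every test, and nRPKM only for this check. The tables hold 52636 genes. Gene coordinates were taken from GENCODE mouse release 21 on GRCm38, which held 52489 of the Ensembl identifiers. As 198 symbols belong to more than 1 identifier, genes were matched by identifier.

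Groups were taken from the genotype and time labels: 3 libraries in each of the 8 groups except WT at T16, which had 2. The labels do not say whether replicates came from separate mice or cultures, or whether libraries of different time points came from the same mice, so p-values measure only the spread between these samples, which may be technical. No pair of replicates was closer than sampling noise (chi-square per degree of freedom 16.51 to 230.71), so none was merged. Totals were 19455080 to 44097733 counts per library.

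Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr on the groups (15782 genes), libraries were scaled by TMM (factors 0.68 to 1.45), and a quasi-likelihood model with robust dispersion was fitted to all 23 libraries with a mean per genotype and time point (common biological coefficient of variation 0.217, median prior degrees of freedom 4.78). Contrasts were KO against WT at each time point and averaged over the 4 time points, LPS against T0 within each genotype, and the change of the genotype difference from T0 to each LPS time point, singly and together. A gene passed the test, or was called, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Adjusted p-values of genes come from this edgeR test unless another tool is named. Log2 fold changes carry a standard error (SE) derived from the quasi-likelihood F statistic. Levels are TMM-scaled CPM, given as mean ± SD, with a prior count of 1 on the log scale.

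The 32 gene lists (inflammation, interferon, COP1 and C/EBP biology, metabolism, stress, antigen presentation, cell cycle, and markers of macrophages and of other cell types, the last including T, B and NK cells and sex-linked genes) were written before the data were examined. Each was tested against all other genes with camera from limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the 32 lists in each comparison), again with an estimated correlation, and with fry, which asks whether the members move one way on balance. Numbers of members that passed are given over all genes tested and adjusted over the list alone. Some lists share members.

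The genes named for each comparison followed a rule set before the data were examined. For KO against WT at a time point these are the 6 largest log2 fold changes in each direction among called genes with a symbol, a mean of at least 5 CPM in the libraries compared and no overlap between the genotypes' CPM; for LPS in WT the 5 largest by the same criteria; for the average the 8 largest in each direction among genes also called at every time point; and for the interaction the 8 lowest p. A gene that this rule selects at T16 is not reported here. Example members of lists were chosen after their values were seen, among members that passed the test. Genes with near-identical copies are marked as uncertain, because the authors' counting could split their reads.

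The calls were tested on simulated data drawn from the real means and library sizes. For KO against WT at T0, 62% of 100 genes changed 2-fold and 94% of 100 changed 4-fold were recovered, with 8 false calls among 15542 genes. For T16 the shares were 47% and 91%, with 9 false calls among 15533 genes. No simulated library stood apart from its group as WT T16 replicate 2 did, so these rates need not hold for the real T16 comparison. camera called the raised list and 0 of 29 unchanged ones in each, but this did not test correlated genes. A GC trend added at T16 gave 224 false calls among 15528 genes, and 7 among 15782 after its removal. For the average over time points, an added effect of the number order (SD 0.3 log2) gave 2 false calls among 15542 genes, and 11 with the order as a block. An equal effect of each presumed culture gave 576 false calls among 15535 in edgeR. limma-voom with libraries of a culture correlated gave 26 among 15782 and recovered 47% of the 2-fold changes, against 84% in edgeR.

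Alternatives set before the data were examined were a 2-fold threshold, DESeq2's median-of-ratios scaling, scaling by library totals, no filter beyond 1 count, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, a fit to the compared groups only, sex of the culture as a covariate, leaving out X and Y genes, and leaving out each library in turn. Those added later were leaving out the 4 WT libraries with Y-linked transcripts, leaving out both T6 libraries in which Saa3 took the most counts, protein-coding genes only, removing smooth trends on GC content and gene length per library (mgcv 1.9.3), the order of the submitters' sample numbers as a block (also in the T6 libraries alone), and limma-voom with a correlation among libraries of a culture presumed from that order. Relatives of pseudogenes were found with BLAST 2.17.0. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. All deposited columns of counts and nRPKM were used.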

Results

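RNA abundance was measured by sequencing in 23 libraries from mouse BMDMs that were either untreated or exposed to LPS, which triggers inflammatory and interferon gene programmes through Toll-like receptor 4. There were 12 libraries labelled KO, 3 at each of T0, T6, T16 and T32, and 11 labelled WT, 3 at each time point except T16, which had 2. Totals ran from 19455080 to 44097733 counts per library. Some libraries stood apart within their group. KO T0 replicate 1 had 0.35% of its counts on mitochondrial genes, against 1.38% to 1.82% in the other T0 libraries. At T6, Saa3 took the most counts in KO replicate 2 and WT replicate 2, which had mitochondrial shares of 0.68% and 1.1% against 0.35% to 0.47% in the other T6 libraries. Saa3 also led in WT T16 replicate 2, where the 10 most abundant genes took 17.39% of counts and the mean correlation with the other T16 libraries was 0.918. For the others it was 0.962 to 0.97. Y-linked transcripts were present in 1 WT library at each time point (T0 replicate 2, T6 replicate 1, T16 replicate 2 and T32 replicate 3), whereas all 12 KO-labelled libraries had Xist RNA.

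Stk40 encodes a pseudokinase that binds the ubiquitin ligase COP1, and its RNA was examined first as a check on the labels. The gene (ENSMUSG00000042608) lies on chromosome 4 at 126103957 to 126141029 in GRCm38. Its RNA was not lower in libraries labelled KO at any time point. At T0 the mean was 56.5 ± 4.8 CPM in libraries labelled KO and 48.1 ± 7.29 CPM in WT (SD, n = 3 each), and at T6 it was 376 ± 18.4 against 313 ± 28.1 CPM (n = 3 each). At T16 it was 161 ± 5.87 (n = 3) against 120 ± 33.4 CPM (n = 2), and at T32 it was 105 ± 2.32 against 82.8 ± 15.1 CPM (n = 3 each). The log2 differences of 0.23 ± 0.15, 0.27 ± 0.15, 0.43 ± 0.17 and 0.34 ± 0.15 (SE) did not pass the edgeR test (adjusted p = 0.71, 0.64, 0.12 and 0.21). Averaged over time points, Stk40 was higher by 0.32 ± 0.08 (edgeR adjusted p = 0.0063), a call that was lost when libraries were scaled by their totals (0.15, edgeR adjusted p = 0.075). With sex of the culture as a covariate the differences at T16 and T32 passed, at 0.60 and 0.45 (edgeR adjusted p = 0.024 and 0.043). So did that at T16 with GC and length trends removed (0.51, edgeR adjusted p = 0.035) and that at T32 without the 4 WT libraries with Y-linked transcripts (0.49, edgeR adjusted p = 0.045). Gene-level counts cannot show whether an exon was removed, so the genotype rests on the labels, and every direction below is that of libraries labelled KO against libraries labelled WT. In WT libraries Stk40 rose with LPS by 2.70 ± 0.16 at T6, 1.31 ± 0.17 at T16 and 0.78 ± 0.15 at T32 (edgeR adjusted p = 2.2e-11, 3.9e-06 and 0.00036). Leaving out single WT libraries moved its difference to 0.12 at T0 (replicate 3), 0.17 or 0.75 at T16 (replicates 1 and 2) and 0.22 at T32 (replicate 1), without a call. Within 10 Mb of Stk40, 272 genes were tested, of which 2.2%, 0.7%, 9.9% and 5.9% were called between genotypes at T0, T6, T16 and T32 and 19.5% in the average. Elsewhere the shares were 1.9%, 0.3%, 7.6%, 6.4% and 22.4%. Fisher's exact test detected no difference (two-sided p = 0.66, 0.19, 0.17, 0.9 and 0.27), but at T6 only 2 called genes lay in the window.

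**Figure D1:**
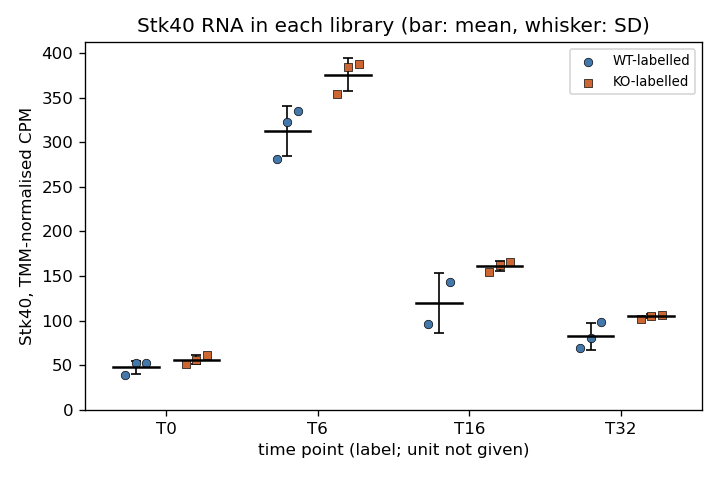
Stk40 RNA in TMM-scaled CPM by time point, each point a library and each bar a group mean, for libraries labelled KO and WT. The KO-labelled mean lies above the WT mean at each of the 4 time points, from 56.5 against 48.1 CPM at T0 to 376 against 313 CPM at T6.

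The LPS response of WT cells gives the background against which the genotypes are compared. At T6, Nos2 (inducible nitric oxide synthase) rose from 2.21 ± 3.57 to 3560 ± 612 CPM, Lipg (endothelial lipase) from 1.98 to 1890 CPM and Acod1, the itaconate-producing enzyme, from 16 ± 8.38 to 9170 ± 623 CPM (n = 3 each). The log2 fold changes were 10.69 ± 1.06, 9.92 ± 0.66 and 9.17 ± 0.39 (edgeR adjusted p = 3.5e-08, 9.4e-11 and 3e-13). Shisa3 and Steap4, near the limit of detection at T0 with 0.0228 and 0.0194 CPM, reached 40 ± 14.4 and 17.1 CPM. Engase fell by 7.28 ± 0.32 and Arhgap19 fell by 6.18 ± 0.19 (edgeR adjusted p = 5.5e-13 and 1.6e-14). Fam214a, Nat8l and Zfp395 fell by 6.38 ± 0.31, 5.63 ± 0.46 and 5.48 ± 0.29. Among the lists, 32 of 33 inflammatory cytokine and chemokine genes rose and 0 fell (32 adjusted over the list alone; median 5.74). They included Tnf at 5.74 ± 0.28, Il1b at 7.47 ± 0.40 and the prostaglandin E synthase Ptges at 7.55 ± 0.25. The numbers were 28 of 29 for the NF-kB pathway (28 adjusted over the list alone; Tnfaip3 4.70 ± 0.21) and 48 of 48 for the interferon response (48 adjusted over the list alone; Ifit1 5.22 ± 0.27). These 3 lists were called by camera (adjusted p = 7.7e-25, 9.3e-29 and 2.3e-42). The calls held with adjusted p = 0.0012, 0.0015 and 0.015 with an estimated correlation. Inflammasome and cell death genes rose in 19 of 25 (19 adjusted over the list alone; Nlrp3 4.37 ± 0.23; camera adjusted p = 1.4e-10, and 0.0067 with an estimated correlation). MHC class I presentation genes rose in 19 of 19 (19 adjusted over the list alone; Tap1 3.21 ± 0.19). Their camera adjusted p was 1.4e-10, and adjusted p = 0.092 with an estimated correlation. In the cell cycle list 26 of 38 genes fell and 4 rose (26 and 4 adjusted over the list alone). Cenpa fell by 2.80 ± 0.25 and Mcm7 fell by 2.47 ± 0.23 (camera adjusted p = 0.011; adjusted p = 0.81 with an estimated correlation). In all, 4302 genes rose and 5030 fell at T6.

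At the later time points most inflammatory and interferon genes of WT cells were again above T0. Saa3, an acute-phase reactant of macrophages, reached 34800 ± 18400 CPM at T16 (n = 2) and 20600 ± 4340 CPM at T32 (n = 3) from 27.3 ± 10.5 CPM. These were log2 fold changes of 10.32 ± 0.64 and 9.57 ± 0.61 (edgeR adjusted p = 3.5e-10 and 5.1e-10). The chemokine Ccl5 rose by 8.77 ± 0.46 and 8.01 ± 0.44, and at T16 Tarm1 and Cxcl9 rose by 7.67 ± 0.38 and 7.19 ± 0.68. At T32 the formyl peptide receptor gene Fpr1 rose by 7.04 ± 0.48 and Acod1 by 6.65 ± 0.35, whereas S100a4 and Ramp1 fell by 5.92 ± 0.52 and 5.90 ± 0.44. At T16 Sult1a1 and the lectin gene Clec10a fell by 5.30 ± 0.48 and 5.11 ± 0.49. Genes near the limit of detection in one of the groups included Arg1 (24.9 against 0.0963 CPM at T0), Slco2b1 (0.0136 against 26.9), Hpgd (0.0596 against 12.9) and Gpr34 (0.15 against 10.6) at T16, and Il23r (14.7 against 0.0273) at T32. Interferon genes rose in 47 of 48 at T16 and at T32 (47 adjusted over the list alone at both; medians 2.63 and 2.37). By camera, adjusted p = 1.9e-50 and 3.7e-40, and adjusted p = 0.017 and 0.056 with an estimated correlation. Inflammatory genes rose in 25 of 33 and in 23 of 33 (25 at both adjusted over the list alone; camera adjusted p = 6.3e-23 and 4.3e-13, and 0.0014 and 0.036 with an estimated correlation). Neutrophil and granulocyte precursor markers fell in 11 of 15 at T32 (11 adjusted over the list alone), among them Ngp by 3.10 ± 0.30 and Ltf by 3.05 ± 0.28. Erythroid markers fell in 10 of 10 (10 adjusted over the list alone). The camera adjusted p was 3e-09 and 0.00036 for these 2 lists, and adjusted p = 0.19 for each with an estimated correlation. At T16, 2970 genes rose and 2710 fell, and at T32 3859 rose and 3461 fell. When libraries were scaled by their totals, the median of all genes moved to −0.94, −0.45 and −0.31 at T6, T16 and T32. The numbers that rose and fell then became 2212 and 9240, 1593 and 5639, and 2286 and 5554.

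In untreated cells, interferon-induced genes were higher in libraries labelled KO. Slfn4 was at 523 ± 228 CPM against 32.1 ± 6.3 CPM in WT and Slfn1 at 157 ± 38.1 against 20.2 ± 3.41 CPM. Ifit2 was at 910 ± 644 against 144 ± 63.1 CPM and Ifi44 at 193 ± 64.3 against 34 ± 6.97 CPM (SD, n = 3 each). The log2 differences were 4.02 ± 0.39, 2.96 ± 0.21, 2.66 ± 0.49 and 2.51 ± 0.22 (edgeR adjusted p = 6e-06, 1.6e-07, 0.0036 and 1.7e-06). Ifi205 and Tgtp2 rose by 2.65 ± 0.45 and 2.49 ± 0.42 (edgeR adjusted p = 0.0018 for each). These 2 and the Slfn genes belong to families of close copies, so their counts are uncertain. Of the 48 interferon-response genes, 41 rose and 0 fell (47 and 0 adjusted over the list alone), with a median of 1.41. These included Zbp1 at 1.59 ± 0.19, Oasl1 at 1.99 ± 0.23 and Oasl2 at 1.14 ± 0.12 (edgeR adjusted p = 5.1e-05, 4.6e-05 and 2.3e-05). camera called the list (adjusted p = 1.8e-132), also with an estimated correlation (adjusted p = 0.00039). In 47 of 48 genes every KO-labelled library exceeded every WT library. Chance gives this at 5% per gene, but genes are not independent. The mean log2 CPM of the list was 7.77, 7.29 and 7.51 in the KO-labelled libraries and 6.07, 6.42 and 5.6 in WT. Without KO T0 replicate 1, the library with the low mitochondrial share, 37 members rose and the median was 1.28. Markers of other cell types moved too. T, B and NK cell markers had a median of 0.99 (0 of 10 by both adjustments) and neutrophil and granulocyte precursor markers one of 0.45 (1 of 15 rose, Ly6g by 1.88 ± 0.47, and 2 adjusted over the list alone). By camera, adjusted p = 0.0024 and 0.0013, and adjusted p = 0.057 and 0.43 with an estimated correlation. Without KO T0 replicate 1 their medians were 1.08 and 0.37 (camera adjusted p = 0.00016 and 0.00013). Stromal markers had a median of −0.82, while 1 of 13 rose (Kdr by 1.75 ± 0.36; 2 adjusted over the list alone; camera adjusted p = 0.64). Without KO T0 replicate 1 it was −0.52 and 0 rose.

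Lower genes were fewer at T0. Ramp1, a receptor activity-modifying protein, was at 7.52 ± 3.81 CPM in libraries labelled KO and 18.8 ± 2.41 CPM in WT. The quinone oxidoreductase gene Nqo1, a target of NRF2, was at 3.6 ± 0.335 against 7.42 ± 0.769 CPM (SD, n = 3 each). They fell by 1.32 ± 0.34 and 1.04 ± 0.16 (edgeR adjusted p = 0.048 and 0.00089). Fam43a, Ifi27, Uck2 and the cyclin F gene Ccnf fell by 1.14 ± 0.27, 0.99 ± 0.22, 0.91 ± 0.23 and 0.71 ± 0.18 (edgeR adjusted p = 0.028, 0.016, 0.046 and 0.046). MHC class I genes rose in 5 of 19 (14 adjusted over the list alone), led by their regulator Nlrc5 at 1.07 ± 0.16 and the peptide transporter gene Tap1 at 0.98 ± 0.18 (edgeR adjusted p = 0.00041 and 0.0033). Macrophage identity genes rose in 2 of 24 (3 rose and 1 fell adjusted over the list alone). These were Fcgr1 by 1.30 ± 0.21 and Siglec1 by 2.03 ± 0.43, the latter lost in a fit to the T0 libraries alone and without KO T0 replicate 1 or WT T0 replicate 3 (edgeR adjusted p = 0.12 and 0.074). Of the 25 inflammasome and cell death genes, 3 rose (6 adjusted over the list alone). Cell cycle genes had a median of −0.57, and 1 of 38 fell (10 adjusted over the list alone). This was Ccnb2, which fell by 1.26 ± 0.32, a call also lost in a fit to the T0 libraries alone. Without KO T0 replicate 1 the median was −0.43 and 0 fell over all genes. Lists called by camera with few or no single members passing were inflammatory cytokines (1 of 33 rose, 4 adjusted over the list alone; median 0.49), NRF2 targets (0 rose and 1 of 24 fell, 1 and 2 adjusted over the list alone; median −0.24) and the integrated stress response (0 of 20 by both adjustments; median −0.28). Others were C/EBP-associated genes (1 of 35 rose, Ptges by 0.84 ± 0.20, and 3 adjusted over the list alone; median 0.28), the lysosome (0 of 38, and 1 rose adjusted over the list alone; median 0.21), Toll-like receptor genes (1 of 28 rose by both adjustments, Tlr3 by 1.19 ± 0.25; median 0.21) and MHC class II (0 of 14 by both; median −0.26). The camera test gave adjusted p = 2.4e-16 for MHC class I, 0.00068 for macrophage identity, 2.9e-05 for the inflammasome list and 3.9e-11 for the cell cycle. It gave adjusted p = 0.0003 for cytokines, 3.3e-05 for NRF2 targets and 0.00051 for the stress response. With an estimated correlation these became adjusted p = 0.057, 0.21, 0.062, 0.18, 0.18, 0.062 and 0.081, so that none of them held. Nor did the C/EBP, lysosome, Toll-like receptor and MHC class II lists, at camera adjusted p = 0.0016, 0.002, 0.00064 and 0.033 and adjusted p = 0.43, 0.52, 0.16 and 0.43 with an estimated correlation. Without KO T0 replicate 1 the lysosome list had a median of 0.02 and no camera call (adjusted p = 0.62). MHC class I, inflammasome and macrophage identity genes then rose in 2, 2 and 1 cases (camera adjusted p = 6.4e-15, 2.2e-06 and 0.0036).

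In all, 289 genes were higher and 18 lower in untreated libraries labelled KO. A fit to the 6 T0 libraries alone called 126 genes and lost Ifit2, Ramp1, Fam43a, Uck2, Ccnf, Siglec1, Ccnb2, Ly6g, Kdr and Ptges (edgeR adjusted p = 0.061 to 0.27). Without WT T0 replicate 3, 164 genes were called. Nqo1 kept its call without any single library. Ramp1, Fam43a, Ifi27, Uck2, Ccnf and Ccnb2 lost theirs without KO T0 replicate 1 (edgeR adjusted p = 0.28, 0.19, 0.098, 0.29, 0.17 and 0.24) or KO T0 replicate 3 (0.21, 0.082, 0.069, 0.1, 0.17 and 0.14). Calls among these 6 were also lost without each of the other T0 libraries, and all but those of Fam43a and Ifi27 without some libraries of later time points (edgeR adjusted p up to 0.066). Without WT T0 replicate 3, Ly6g, Tlr3 and Ptges lost theirs (edgeR adjusted p = 0.21, 0.064 and 0.12), and Kdr and Tlr3 did without KO T0 replicate 1 (0.094 and 0.071). Without KO T0 replicate 2, Ly6g was at 1.07 and Ptges at 0.63 (edgeR adjusted p = 0.22 and 0.15). Ly6g, Kdr and Ptges also lost their calls without WT T0 replicate 1 or 2, and Ptges without KO T0 replicate 3. Ly6g also did without some libraries of later time points (edgeR adjusted p up to 0.055). Scaling by library totals moved the median of all genes by −0.15 at T0 and by −0.19, −0.18 and −0.2 at T6, T16 and T32. Directions of lists are given relative to TMM scaling, with named exceptions where a printed median turned sign or reached 0.

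**Figure D2:**
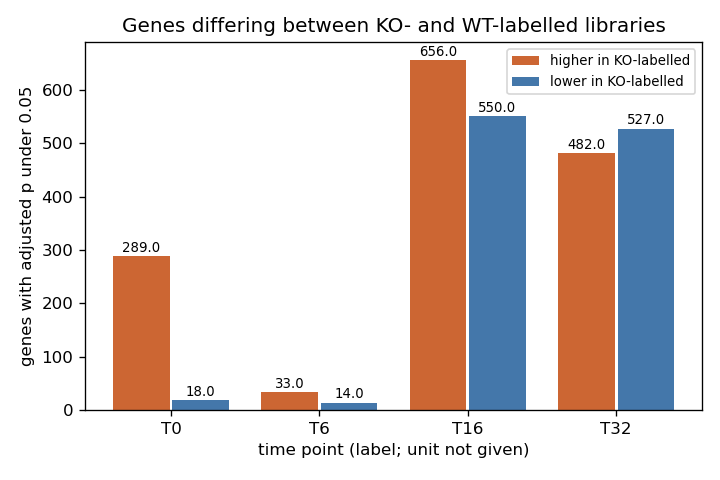
Number of genes called higher and lower in libraries labelled KO than in WT at each time point (edgeR, Benjamini-Hochberg adjusted p under 0.05, 15782 genes tested). There were 289 higher and 18 lower genes at T0, 33 and 14 at T6, 656 and 550 at T16, and 482 and 527 at T32.

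At T6, where more WT genes had responded to LPS than at T16 or T32, few genes differed between genotypes. Arg2, the mitochondrial arginase, was at 23.8 ± 5.87 CPM in libraries labelled KO and 7.57 ± 1.64 CPM in WT, and Pgf (placental growth factor) was at 17.4 ± 1.74 against 5.61 ± 0.495 CPM. The C-mannosyltransferase gene Dpy19l3 was at 30.2 ± 2.7 against 11.2 ± 1.51 CPM and Pdpn (podoplanin) at 714 ± 50.8 against 281 ± 27 CPM (SD, n = 3 each). They rose by 1.65 ± 0.26, 1.63 ± 0.24, 1.44 ± 0.17 and 1.35 ± 0.19 (edgeR adjusted p = 0.0061, 0.0034, 0.00028 and 0.0019). Ly6a (Sca-1) and the POU-domain transcription factor gene Pou3f1 both rose by 1.24, with SEs of 0.24 and 0.26 (edgeR adjusted p = 0.027 and 0.047). The potassium channel gene Kcnk13 fell by 1.22 ± 0.13, from 15.6 ± 0.248 to 6.69 ± 0.29 CPM (edgeR adjusted p = 8.9e-05). Rab3il1, Paqr7, Tmem268 and Cnst fell by 1.17 ± 0.23, 0.92 ± 0.15, 0.91 ± 0.16 and 0.89 ± 0.15, and Tfeb, a transcription factor of lysosomal genes, by 0.89 ± 0.18 (edgeR adjusted p = 0.034, 0.006, 0.013, 0.011 and 0.034). Nqo1 fell by 1.06 ± 0.18, much as at T0 (edgeR adjusted p = 0.0098).

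The lists at T6 held small shifts in which hardly any single gene passed. Cholesterol synthesis genes had a median of −0.56 with 0 of 24 below the threshold over all genes (9 fell adjusted over the list alone; camera adjusted p = 4.7e-09). Interferon genes had a median of 0.33 (0 of 48 by both adjustments), inflammatory cytokines 0.44 (0 of 33 by both) and MHC class I genes 0.31 (0 of 19, and 4 adjusted over the list alone), with camera adjusted p = 2.9e-10, 5.8e-08 and 5.8e-08. Neutrophil markers, at a median of 0.66, had 0 of 15 over all genes and 3 adjusted over the list alone (camera adjusted p = 4.4e-06). None of these 5 lists held: adjusted p = 0.2, 0.24, 0.13, 0.2 and 0.2 with an estimated correlation, in the order given. T, B and NK cell markers were at 0.70 (0 of 10 by both adjustments; camera adjusted p = 0.063), and at 0.90 without both libraries led by Saa3 (camera adjusted p = 0.0098). Libraries of the genotypes at the same place in the order of the submitters' sample numbers form 3 pairs, a hint from the data, not the design. Within them the mean log2 CPM of cholesterol synthesis genes differed by −0.73, 0.25 and −0.89, the second pair going the other way. Interferon genes differed by 0.32, 0.33 and 0.35, cytokines by 0.66, 0.34 and 0.73 and MHC class I genes by 0.45, 0.37 and 0.33. Neutrophil markers differed by 0.25, 1.24 and 0.18. An exact sign-flip test over the pairs gave two-sided p = 0.5 for cholesterol synthesis and 0.25, the smallest that 3 pairs allow, for the other 4. With the order as a block, camera on all libraries gave adjusted p = 0.19, 0.24, 0.059, 0.071 and 0.24 with an estimated correlation, and on the T6 libraries alone 0.64, 0.3, 0.3, 0.46 and 0.58, for the 5 lists in the order first given. In that last fit 11 of 48 interferon genes rose and 1 fell, 10 of 33 cytokine genes, 5 of 19 MHC class I genes and 4 of 13 neutrophil markers rose, and 1 of 24 cholesterol synthesis genes fell. The blocked fry tests, which do not compare a list with other genes, gave adjusted p = 0.084, 0.11, 0.022, 0.015 and 0.11 on all libraries and 0.49, 0.032, 0.089, 0.078 and 0.41 on the T6 libraries alone. T, B and NK cell markers had a median of 0.03 in the T6 libraries alone with the block (0 of 7 called).

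The edgeR test at T6 called 33 genes higher and 14 lower (1492 at an unadjusted p under 0.05). A fit to the 6 T6 libraries alone called 0 genes (722 at an unadjusted p under 0.05), while DESeq2 on all libraries called 269. Without both libraries led by Saa3, 25 were called, and with the order of the submitters' sample numbers as a block, 72. With that block the T6 libraries alone gave 401 (342 higher and 59 lower, with 2 residual degrees of freedom), without Rab3il1 (edgeR adjusted p = 0.056). Leaving out single libraries gave 15 and 18 genes without KO T6 replicate 3 and WT T6 replicate 1, 29 without KO T0 replicate 3 and 31 without KO T16 replicate 2. It gave 31, 31 and 27 without KO T32 replicates 2, 3 and 1, and 73 without either WT T16 library. Arg2, Pgf, Dpy19l3, Pdpn and Kcnk13 kept their calls without any single library. Pou3f1, Rab3il1, Tmem268, Cnst, Tfeb and Paqr7 lost theirs without KO T6 replicate 3 (edgeR adjusted p = 0.095, 0.23, 0.095, 0.065, 0.22 and 0.052). Ly6a and Nqo1 did without WT T6 replicate 1 (edgeR adjusted p = 0.1 and 0.075), as did the first 5 of those 6. Calls among these 8 were also lost without KO T6 replicate 2 or WT T6 replicates 2 or 3, and those of Pou3f1, Rab3il1 and Tfeb without some libraries of other time points. Scaling by library totals gave 16 higher and 106 lower and turned the medians of the lysosome and Toll-like receptor lists, 0.14 and 0.16, to −0.05 and −0.03. Without both libraries led by Saa3 the lysosome median was 0.05 (camera adjusted p = 0.45).

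At T16, the largest differences among the higher genes that met the naming rule were those of Htr2b, Slamf1 and Tspan13. The serotonin receptor gene Htr2b was at 35.2 ± 1.06 CPM (n = 3) against 4.39 ± 0.372 CPM in WT (n = 2), and the tetraspanin gene Tspan13 was at 40.1 ± 4.19 against 6.64 ± 0.269 CPM. Slamf1 (CD150) was at 28.9 ± 12 against 4.4 ± 0.946 CPM and Il7r, the interleukin 7 receptor gene, at 133 ± 16.9 against 23.5 ± 14.9 CPM. The log2 differences were 3.0 ± 0.36, 2.60 ± 0.22, 2.72 ± 0.42 and 2.50 ± 0.54 (edgeR adjusted p = 0.00017, 3e-06, 0.0013 and 0.0093). Gprc5b and Tmem154 rose by 2.51 ± 0.47 and 2.37 ± 0.30 (edgeR adjusted p = 0.004 and 0.00027). Tmem176b was at 72.7 ± 9.91 CPM against 259 ± 142 CPM and fell by 1.83 ± 0.43, and its neighbour Tmem176a fell by 1.77 ± 0.49 (edgeR adjusted p = 0.015 and 0.032). Rcn3, Fcrls and Fam213b fell by 1.78 ± 0.50, 1.68 ± 0.47 and 1.44 ± 0.29 (edgeR adjusted p = 0.035, 0.033 and 0.0062).

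Among the lists at T16, extracellular matrix and protease genes rose in 6 of 32 (11 rose and 2 fell adjusted over the list alone), with Mmp8 at 2.25 ± 0.34 and Mmp13 at 1.54 ± 0.33 (edgeR adjusted p = 0.0012 and 0.0093). Interferon genes rose in 9 of 48 (15 rose and 1 fell adjusted over the list alone), with Gbp3 at 1.32 ± 0.29 and Ifi44 at 0.97 ± 0.24. Inflammasome and cell death genes rose in 7 of 25 (12 rose and 4 fell adjusted over the list alone), including Mdm2 at 0.92 ± 0.18 and Aim2 at 0.74 ± 0.15. C/EBP-associated myeloid genes rose in 3 of 35 (11 rose and 1 fell adjusted over the list alone), which were Mmp8, Il1rn and Ptges. The antagonist gene Il1rn rose by 1.75 ± 0.33 and Ptges by 1.13 ± 0.21, the 2 called among 33 inflammatory genes (2 adjusted over the list alone). Fatty acid oxidation and respiration genes fell in 4 of 26 (5 adjusted over the list alone) and cell cycle genes in 4 of 38 (5 adjusted over the list alone; Mcm7 fell by 0.93 ± 0.23). Cholesterol synthesis genes fell in 3 of 24 (3 adjusted over the list alone; Dhcr7 fell by 0.94 ± 0.19). Shmt2 of the serine and one-carbon pathway fell by 0.93 ± 0.15 (edgeR adjusted p = 0.0015). The camera adjusted p for these lists was 0.0011, 1.4e-07, 0.0033, 0.0033, 0.0041, 0.00026, 0.0033 and 0.022. With an estimated correlation it was adjusted p = 0.4, 0.48, 0.4, 0.5, 0.48, 0.4, 0.58 and 0.58. Markers of other cell types had positive medians beside these. Neutrophil and granulocyte precursor markers, which include Mmp8, were at 0.60 (1 of 15 rose, 4 adjusted over the list alone). Dendritic cell and mast cell markers were at 0.72 and 0.92 (0 of 13 and 0 of 4 by both adjustments), and T, B and NK cell markers at 0.56 (1 of 10 rose, Nkg7 by 2.98 ± 0.82; 1 and 1 lower adjusted over the list alone). Their camera adjusted p was 0.0033, 0.34, 0.22 and 0.22, and the first became adjusted p = 0.48 with an estimated correlation. Stromal markers were at −0.44 with 1 of 13 higher (Kdr by 1.78 ± 0.40; 2 adjusted over the list alone; camera adjusted p = 0.53). Without WT replicate 2 the neutrophil markers had a median of 1.28 and the C/EBP list one of 0.64. The T, B and NK cell markers were then at 0.93.

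The edgeR test at T16 called 656 genes higher and 550 lower, but without WT replicate 2 it called 109, of which 95 were among those called with both. It then lost Gprc5b, Il7r, Nkg7 and Kdr, which were still at 2.31, 1.97, 3.19 and 1.5. The lower genes Tmem176b, Rcn3, Tmem176a, Fcrls and Fam213b moved closer to 0, to −1.13, −1.1, −1.08, −0.73 and −0.83 (edgeR adjusted p = 0.32, 0.44, 0.44, 0.63 and 0.22). Without WT replicate 1 it called 3537. The compared libraries alone gave 9 genes, which among those named here included Htr2b, Tspan13 and Mmp8. Leaving out KO replicate 1 or 3 gave 419 or 482. Without WT replicate 2 the interferon list had a median of 0.67 with 0 genes called, while camera no longer called the cholesterol synthesis list (adjusted p = 0.065). The genes called were then 1 higher of the matrix, inflammasome and inflammatory lists, 2 higher of the C/EBP list, and 0 of the fatty acid oxidation, cell cycle and cholesterol synthesis lists. Of the list members named here, Mmp8, Aim2, Ptges and Shmt2 stayed called without WT replicate 2. Tmem176b, Rcn3, Tmem176a, Fcrls, Ifi44 and Mcm7 also lost their calls without KO replicate 1 (edgeR adjusted p = 0.065, 0.14, 0.12, 0.092, 0.058 and 0.065) or 3 (0.062, 0.12, 0.11, 0.12, 0.06 and 0.089). Nkg7 did without either of those or WT replicate 1 (edgeR adjusted p = 0.077, 0.11 and 0.091). Scaling by totals gave 344 genes higher and 1233 lower.

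At T32, Htr2b and Tspan13 had the largest differences among the higher genes that met the naming rule. Htr2b was at 37.1 ± 7.31 CPM in libraries labelled KO against 4.1 ± 1.94 CPM in WT, and Tspan13 at 50.3 ± 8.6 against 6.42 ± 0.665 CPM. Il7r was at 141 ± 44.4 against 23.4 ± 11.2 CPM and Mmp8, the neutrophil collagenase, at 116 ± 32.4 against 18.9 ± 2.67 CPM (SD, n = 3 each). They rose by 3.18 ± 0.31, 2.97 ± 0.19, 2.59 ± 0.46 and 2.62 ± 0.29 (edgeR adjusted p = 6.9e-06, 1.8e-08, 0.002 and 2.3e-05). Gprc5b and the inhibitory ligand gene Cd200 rose by 2.69 ± 0.41 and 2.58 ± 0.30 (edgeR adjusted p = 0.00054 and 3.1e-05). Tmem176b was at 25.3 ± 3.03 CPM against 181 ± 81 CPM and Tmem176a at 12.2 ± 2.03 against 72.2 ± 29.8 CPM. They fell by 2.84 ± 0.42 and 2.56 ± 0.47 (edgeR adjusted p = 0.00036 and 0.0026). Fcrls fell by 2.65 ± 0.46 and Igfbp4, an insulin-like growth factor binding protein, by 2.02 ± 0.28 (edgeR adjusted p = 0.0016 and 0.00023). Rnaset2a fell by 2.30 ± 0.22 and mt-Co2 by 2.41 ± 0.49 (edgeR adjusted p = 6.9e-06 and 0.0054), both uncertain because of copies. Rnaset2b was at −0.79 ± 0.30 (edgeR adjusted p = 0.14). The RNA of mt-Co2, a mitochondrial gene with copies in the nuclear genome, was at 1.92 against 10.2 ± 2.16 CPM while mt-Co1 was at −0.51 (edgeR adjusted p = 0.54).

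**Figure D3:**
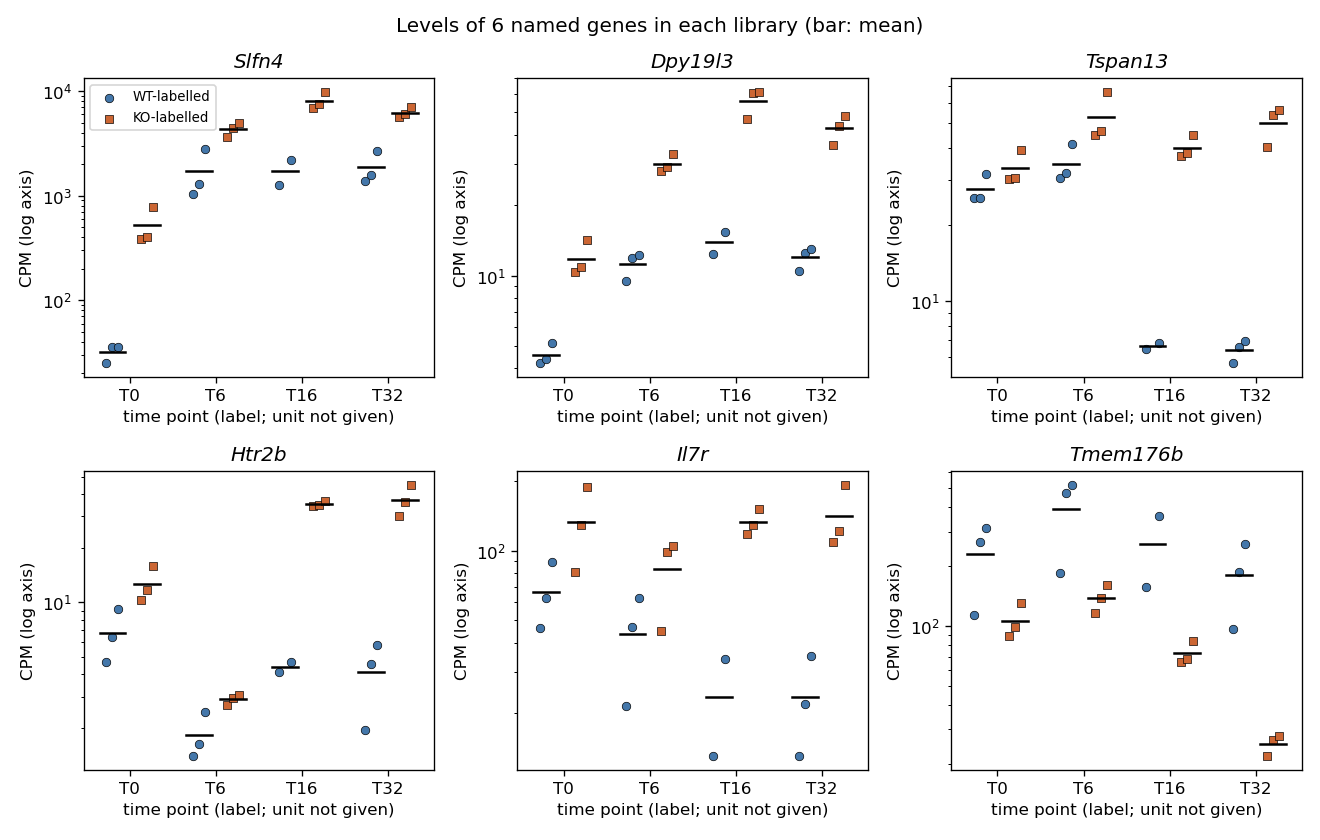
CPM of Slfn4, Dpy19l3, Tspan13, Htr2b, Il7r and Tmem176b by time point on a log axis, each point a library and each bar a group mean, for libraries labelled KO and WT. At T32 Tspan13 was at 50.3 CPM in libraries labelled KO and 6.42 CPM in WT, and at T0 Slfn4 was at 523 and 32.1 CPM.

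Inflammatory genes at T32 rose in 4 of 33 (8 adjusted over the list alone; median 0.69), among them Ptges by 1.89 ± 0.19 and Il1rn by 2.10 ± 0.28 (edgeR adjusted p = 8.9e-06 and 0.00016). The other 2, Il1a at 1.44 ± 0.38 and Nos2 at 2.51 ± 0.73 (edgeR adjusted p = 0.028 and 0.045), lost their calls without a filter on low counts and without several single libraries (edgeR adjusted p up to 0.12 and 0.2). Extracellular matrix and protease genes rose in 10 of 32 (10 adjusted over the list alone), with Mmp13 at 1.83 ± 0.29. C/EBP-associated genes rose in 9 of 35 with 1 lower (12 and 1 adjusted over the list alone; F10 1.55 ± 0.19). Lysosomal genes rose in 4 of 38 (9 adjusted over the list alone; the cathepsins Ctsl 1.33 ± 0.17 and Ctsk 1.44 ± 0.31). Interferon genes rose in 9 of 48 (22 rose and 1 fell adjusted over the list alone; Gbp3 1.20 ± 0.25) and NF-kB genes in 3 of 29 (4 adjusted over the list alone; Cflar 0.77 ± 0.14). Alternative activation genes rose in 3 of 21 (5 rose and 1 fell adjusted over the list alone), with the transcription factor gene Klf4 at 1.64 ± 0.26 and the beta-glucan receptor gene Clec7a at 1.05 ± 0.18. The camera adjusted p was 3.8e-09, 1.7e-06, 3.3e-08, 2.4e-06, 4.8e-14, 0.005 and 0.014 for these lists in turn. It was 0.12, 0.12, 0.21, 0.26, 0.26, 0.38 and 0.12 with an estimated correlation.

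Markers of other cell types at T32 moved beside these. Neutrophil and granulocyte precursor markers had a mean log2 CPM of 1.66 ± 0.24 in libraries labelled KO and 0.97 ± 0.23 in WT (SD, n = 3 each) and a median difference of 0.43. Of them 2 of 15 rose, Mmp8 and the lactoferrin gene Ltf by 0.99 ± 0.26 (5 adjusted over the list alone; camera adjusted p = 3.8e-05, and adjusted p = 0.26 with an estimated correlation). T, B and NK cell markers were at 0.52, and 1 of 10 fell by both adjustments, the B cell receptor gene Cd79b by 1.27 ± 0.35. Mast cell markers were at 0.60 (0 of 4 by both). Stromal markers had a median of −0.60 and a mean of −0.22, while camera gave their direction as up. Of them 2 of 13 rose by both adjustments, Kdr by 1.84 ± 0.35 and Thy1 by 1.60 ± 0.47. Erythroid markers were at 0.05 (1 of 10 fell by both, the erythropoietin receptor gene Epor by 1.5 ± 0.44) and dendritic cell markers at 0.00 (0 of 13 by both). Osteoclast markers were at 0.22 (1 of 8 rose, Ctsk, and 2 adjusted over the list alone) and macrophage identity genes at 0.03 (1 of 24 rose by both). With scaling by library totals the medians of the macrophage, dendritic cell and erythroid lists were −0.16, −0.1 and 0. The camera adjusted p of these last 7 lists was 0.5, 0.13, 0.93, 0.83, 0.58, 0.093 and 0.5. Ltf, Cd79b, Thy1 and Epor lost their calls without several single libraries (edgeR adjusted p up to 0.18, 0.12, 0.22 and 0.26), and Thy1 and Epor also with sex of the culture as a covariate (0.061 and 0.056). Epor was lost in a fit to the 6 libraries alone too (0.067).

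In the other direction at T32, cell cycle genes fell in 5 of 38 (17 adjusted over the list alone; median −0.59). Rrm2 fell by 1.54 ± 0.31 and Aurkb by 1.18 ± 0.25. Cholesterol synthesis genes fell in 3 of 24 (4 adjusted over the list alone; Dhcr7 fell by 0.82 ± 0.17) and glycolysis genes in 6 of 25 with 2 higher (7 and 3 adjusted over the list alone). Among the last were Aldoc at −1.24 ± 0.24, Pgam1 at −2.28 ± 0.38 and Pgk1 at −1.27 ± 0.31. Pgam1 and Pgk1 are uncertain because of processed copies and may carry part of the list's call. LXR target genes fell in 4 of 15 (4 adjusted over the list alone), with Acsl3, an acyl-CoA synthetase gene, at −0.99 ± 0.20. By camera, adjusted p for these 4 lists was 4.1e-08, 0.0022, 0.0034 and 0.089. It was 0.26, 0.48 and 0.33 with an estimated correlation for the first 3. Of the 527 lower genes, 212 (40.2%) were annotated pseudogenes, whose median over all 1429 tested was −0.39, and 482 genes were higher. ERK pathway targets rose in 4 of 31 (4 adjusted over the list alone; Dusp1 1.09 ± 0.19; camera adjusted p = 0.047, and adjusted p = 0.51 with an estimated correlation). Their median of 0.06 turned to −0.13 with scaling by library totals, which gave 303 genes higher and 1201 lower. Leaving out a T32 library gave 363 calls without WT replicate 2, 568 without WT replicate 1, and 643, 431 and 490 without KO replicates 1, 2 and 3. A fit to the 6 libraries alone gave 2688 and lost Mmp13 and Nos2 (edgeR adjusted p = 0.061 and 0.095). Without WT replicate 2, Ctsk, Gbp3 and Dhcr7 were no longer called (edgeR adjusted p = 0.059, 0.058 and 0.056), nor was Aurkb without KO replicate 3 (0.05).

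**Figure D4:**
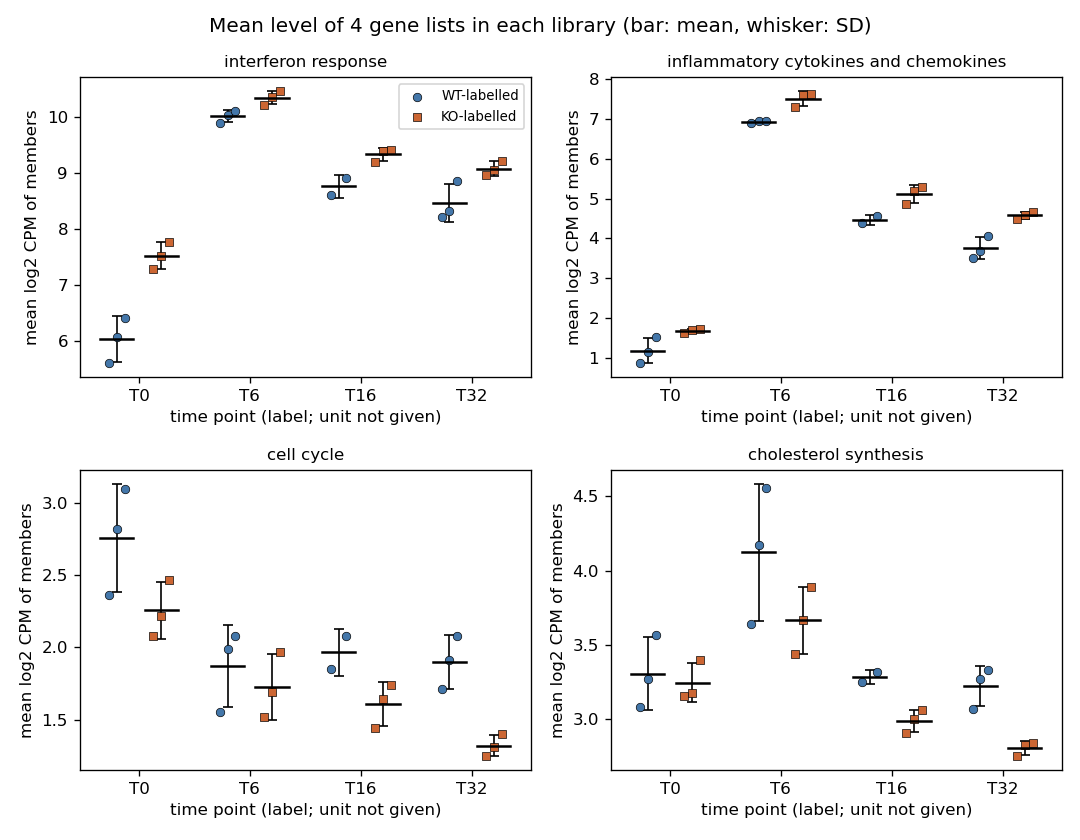
Mean log2 CPM of the interferon, inflammatory, cell cycle and cholesterol synthesis lists by time point, each point a library, for libraries labelled KO and WT. At T0 the interferon list lay at 7.52 ± 0.24 in libraries labelled KO and 6.03 ± 0.41 in WT (SD, n = 3 each).

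Averaged over the time points, 1904 genes were higher and 1623 lower in libraries labelled KO. A difference at a single time point can carry such an average, and only 7 genes, all higher, were called at every time point. Dpy19l3 rose by 1.66 ± 0.09, from 10.1 ± 3.84 CPM in WT (n = 11) to 35.2 ± 17.7 CPM (n = 12), and Ly6a by 1.21 ± 0.12, from 413 ± 217 to 899 ± 247 CPM (edgeR adjusted p = 4.6e-10 and 1.9e-06). Pou3f1 rose by 1.63 ± 0.14, the angiopoietin gene Angpt2 by 1.38 ± 0.14, the mucolipin gene Mcoln2 by 0.75 ± 0.07 and Fam46a by 0.65 ± 0.07 (edgeR adjusted p = 5.6e-07, 1.4e-06, 6.2e-07 and 3.3e-06). The seventh has only a clone-based name. Pou3f1 lies on chromosome 4 at 124656807 to 124660655, inside the window around Stk40. Scaling by library totals gave 940 higher and 4656 lower genes.

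Immune lists were mostly higher in the average. Interferon genes rose in 46 of 48 with 1 lower (46 and 1 adjusted over the list alone; median 0.71). Ifi44 was at 1.21 ± 0.11, Ifit1 at 1.10 ± 0.12 and Cxcl9, the lower one, at −1.0 ± 0.27 (edgeR adjusted p = 6.2e-07, 4.2e-06 and 0.012). MHC class I genes rose in 13 of 19 (13 adjusted over the list alone; Nlrc5 0.68 ± 0.08) and inflammatory genes in 14 of 33 (17 adjusted over the list alone; Ptges 1.06 ± 0.10, Il1rn 1.40 ± 0.15, Il10 1.13 ± 0.22). NF-kB genes rose in 9 of 29 with 1 lower (9 and 1 adjusted over the list alone; Cflar 0.61 ± 0.07), and Toll-like receptor genes in 9 of 28 with 1 lower (13 and 1 adjusted over the list alone; Tlr3 0.91 ± 0.13, Tlr1 −0.29 ± 0.09). Inflammasome and cell death genes rose in 15 of 25 with 4 lower (15 and 4 adjusted over the list alone; Casp4 0.56 ± 0.08, Pycard −0.41 ± 0.11), and C/EBP-associated genes in 14 of 35 with 1 lower (15 and 1 adjusted over the list alone; Marco −1.73 ± 0.36). Matrix and protease genes rose in 15 of 32 with 1 lower (16 and 1 adjusted over the list alone; Mmp13 1.15 ± 0.15, the inhibitor Timp3 −1.07 ± 0.27), and lysosomal genes in 18 of 38 with 1 lower (21 and 2 adjusted over the list alone; Ctsl 0.94 ± 0.09, Ctsf −0.56 ± 0.15). In camera tests of these 9 lists, adjusted p was 1.3e-40, 4.5e-09, 8.5e-08, 0.0011, 0.001, 8.9e-06, 4.9e-07, 1.1e-05 and 1.3e-05. It became adjusted p = 0.097, 0.15, 0.097, 0.26, 0.16, 0.097, 0.16, 0.15 and 0.23 with an estimated correlation. With sex of the culture as a covariate, Cxcl9, Tlr1, Pycard and Ctsf lost their calls, and Marco did without the 4 WT libraries that had Y-linked transcripts. Without WT T0 replicate 1, Cxcl9 and Tlr1 lost theirs (edgeR adjusted p = 0.052 and 0.051). Tlr1 also did without WT T0 replicate 2 or WT T16 replicate 2 (edgeR adjusted p = 0.052 and 0.058), and Pycard without the latter (0.052). MHC class II genes fell in 5 of 14 with 1 higher (5 and 1 adjusted over the list alone; H2-Eb1 −0.64 ± 0.15; camera adjusted p = 0.27).

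Metabolic and growth lists were mostly lower. Cell cycle genes fell in 18 of 38 (22 adjusted over the list alone; median −0.40), among them Ube2c, which fell by 1.19 ± 0.19, and Cdk1, which fell by 0.62 ± 0.11. Cholesterol synthesis genes fell in 8 of 24 (10 adjusted over the list alone; Mvd fell by 0.74 ± 0.12). Genes of fatty acid oxidation and respiration fell in 10 of 26 with 1 higher (14 and 1 adjusted over the list alone; Ndufa9 fell by 0.25 ± 0.06, a call lost with sex as a covariate, and by 0.16 without WT T16 replicate 2). NRF2 targets fell in 8 of 24 with 1 higher (8 and 2 adjusted over the list alone; Nqo1 fell by 0.70 ± 0.09). Integrated stress response genes fell in 7 of 20 (8 fell and 1 rose adjusted over the list alone), with Shmt2 at −0.61 ± 0.07 and Psat1 at −0.56 ± 0.11. The camera adjusted p of these 5 lists was 1.6e-07, 0.00022, 0.00039, 0.0062 and 0.0062. With an estimated correlation it was adjusted p = 0.23, 0.32, 0.15, 0.17 and 0.16. Lists without a camera call were glycolysis (9 of 25 fell and 2 rose by both adjustments; adjusted p = 0.069) and glycogen metabolism (2 of 15 fell and 1 rose by both; 0.57). Others were LXR targets (4 of 15 fell and 1 rose by both; adjusted p = 0.29) and the unfolded protein response (5 of 22 fell and 2 rose by both; 0.12). Neither were the COP1 ligase and Tribbles genes called (3 of 11 fell and 2 rose by both adjustments; Trib1 0.48 ± 0.11; camera adjusted p = 0.68). The COP1 substrate transcription factors were not called either (3 of 12 rose and 3 fell, 4 and 3 adjusted over the list alone; adjusted p = 0.9). The median of the substrates was 0.04 (−0.12 with scaling by library totals) and the mean −0.10, with Etv1 at 0.56 ± 0.11, Cebpd at −0.84 ± 0.19 and Etv4 at −1.58 ± 0.37, the last lost without the 4 WT libraries that had Y-linked transcripts. ERK targets (8 of 31 rose and 2 fell, 8 and 3 adjusted over the list alone; camera adjusted p = 0.4) had a median of 0.02 (−0.16 with scaling by library totals) and a mean of −0.02. Alternative activation genes rose in 5 of 21 with 1 lower by both adjustments (camera adjusted p = 0.14), and their median of 0.14 turned to −0.05 with scaling by library totals.

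Cell type markers moved in several directions in the average. Macrophage identity genes rose in 7 of 24 (10 adjusted over the list alone; median 0.12, and −0.06 with scaling by library totals; camera adjusted p = 0.033, and adjusted p = 0.37 with an estimated correlation). Neutrophil and granulocyte precursor markers rose in 7 of 15 (7 adjusted over the list alone), with Mmp8 at 1.64 ± 0.15, Ltf at 0.88 ± 0.13 and Retnlg at 1.55 ± 0.25. T, B and NK cell markers rose in 5 of 10 with Cd79b lower at −0.77 ± 0.18 (6 and 1 adjusted over the list alone). The 2 lists had camera adjusted p = 2.2e-06 and 0.033. With an estimated correlation it was adjusted p = 0.16 and 0.15. Lists that camera did not call were dendritic cells (1 of 13 rose and 2 fell, 5 and 2 adjusted over the list alone; Batf3 −0.84 ± 0.23; adjusted p = 0.47) and stroma (3 of 13 rose and 3 fell by both adjustments; Kdr 1.60 ± 0.18, Acta2 −1.10 ± 0.32; 0.94). Erythroid markers (0 of 10 rose and 1 fell by both; camera adjusted p = 0.52) and mast cell markers (2 of 4 rose by both; Kit 0.80 ± 0.20; 0.078) were not called. Nor were osteoclast markers (2 of 8 rose, 3 adjusted over the list alone; Ctsk 0.57 ± 0.16; camera adjusted p = 0.16) or sex-linked genes (0 of 5 rose and 4 fell by both; 0.31). With sex as a covariate, Batf3, Acta2, Kit and Ctsk lost their calls, and without WT T16 replicate 2 Batf3 and Acta2 did (edgeR adjusted p = 0.069 and 0.055). Cd79b lost its call without the 4 WT libraries that had Y-linked transcripts (edgeR adjusted p = 0.088).

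The size of the LPS response was compared between the genotypes over all 15782 genes, which are not independent replicates. The log2 responses in libraries labelled KO and in WT had a Pearson correlation of 0.924 at T6, 0.856 at T16 and 0.841 at T32 (Spearman 0.931, 0.839 and 0.848). The slopes of the KO-labelled on the WT response were 0.91, 0.837 and 0.772, and those of the WT on the KO-labelled response 0.937, 0.876 and 0.916. All lay below 1, so they do not show in which genotype the response was larger. Of the genes called in both, 8223 of 8223, 4391 of 4398 and 4757 of 4777 moved the same way. In libraries labelled KO, 4142 genes rose and 5111 fell at T6, 3226 rose and 3677 fell at T16, and 2868 rose and 3153 fell at T32. With scaling by library totals these were 2007 and 9492, 1704 and 7033, and 1484 and 5770. Genes induced at least 2-fold by LPS, judged on the mean of both genotypes, tended to be higher in libraries labelled KO. Of them, 23 were called higher and 0 lower at T6, 244 and 7 at T16, and 208 and 102 at T32 (medians 0.23, 0.41 and 0.21 over 3036, 1995 and 1982 genes). Genes repressed at least 2-fold were called higher in 1, 41 and 37 cases and lower in 12, 85 and 97 (medians −0.2, −0.21 and −0.2 over 3672, 2025 and 2182 genes). Fisher's exact test of call direction against class gave two-sided p = 1e-08, 6.4e-44 and 1.3e-14, as if genes were independent. Pseudogenes raised in WT at T32 may be among the 102, which was not tested.

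Genes whose genotype difference changed with time were tested by the interaction. The difference in Tspan13 grew over the time course, from 0.27 at T0 and 0.61 at T6 to 2.60 and 2.97 at T16 and T32. That of Htr2b grew from 0.90 and 0.66 to 3.0 and 3.18 (edgeR adjusted p of the joint interaction = 1.1e-05 and 0.0079). The differences of the interferon-induced Slfn1 shrank from 2.96 at T0 to 0.59, 0.57 and 0.60, and those of Ms4a4c from 2.38 to 0.52, 0.65 and 0.72 (edgeR adjusted p = 4e-04 and 0.0056). Lair1, an inhibitory collagen receptor gene, went from 0.90 to −0.01, −0.24 and 0.04, and Arhgap26 from 0.30 to 1.07, −0.23 and −0.75 (edgeR adjusted p = 0.0034 for each). Tns1 (tensin) went from 0.41 and 0.08 to 1.40 and 1.26, and Rnaset2a, an uncertain gene, was at 0.06, 0.02 and 0.06 before it reached −2.30 at T32 (edgeR adjusted p = 0.0056 and 0.0015). The interferon list had medians of −1.09, −0.95 and −0.89 for the change from T0 to T6, T16 and T32. Of its 48 genes, 39, 31 and 30 fell adjusted over the list alone and 4, 1 and 4 over all genes. The camera adjusted p for these changes was 1e-80, 2.1e-31 and 3.3e-31, and adjusted p = 0.0065, 0.13 and 0.14 with an estimated correlation. The change from T0 was called for 16 genes at T6 (1 up, 15 down), 11 at T16 (4 up, 7 down) and 61 at T32 (14 up, 47 down), and the joint test called 72. Leaving out single libraries moved these numbers between 1 and 21, 4 and 1061, 29 and 94, and 25 and 639. The highest T16 and joint numbers came without WT T16 replicate 1, and the lowest at T6 without WT T0 replicate 3.

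Calls between genotypes recurred across time points more often than independent lists of those sizes would. The T16 and T32 comparisons, which have no library in common, shared 273 higher genes, where 20 would be expected, and 134 lower genes, where 18.4 would be expected. T0 shared 96 higher genes with T16 and 74 with T32 (12 and 8.8 expected), and T6 shared 8 with T0, 22 with T16 and 15 with T32 (0.6, 1.4 and 1 expected). Shared lower genes were few outside T16 and T32, with 1 for T0 and T6, 2 for T0 and T16, 4 for T0 and T32, 1 for T6 and T16 and 3 for T6 and T32 (0, 0.6, 0.6, 0.5 and 0.5 expected). T6 also had 1 gene called in opposite directions with T16 and 2 with T32. The expected numbers assume that the comparisons are independent. Libraries at the same place in the order of the submitters' sample numbers deviated together in 14 of 15 pairs of WT libraries of different time points (mean correlation 0.39), so the comparisons may share cultures, and how much of the excess comes from that was not separated.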

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

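The counts over other groupings of libraries, the test of trace LPS and the use of other fits to weigh the interferon pattern were chosen after the results were seen. The interaction contrasts, the sex covariate and leaving out single libraries were set before. The genotype difference changed between time points for 72 genes in the joint interaction test (edgeR, Benjamini-Hochberg adjusted), and from T0 to T6, T16 and T32 for 16, 11 and 61 genes. The 8 genes with the lowest joint p were Tspan13 (adjusted p = 1.1e-05), Slfn1 (4e-04), Rnaset2a (0.0015), Arhgap26 and Lair1 (0.0034 each), Tns1 and Ms4a4c (0.0056 each) and Htr2b (0.0079). Tspan13, Htr2b and Tns1 differed by 2.97, 3.18 and 1.26 at T32 against 0.27, 0.90 and 0.41 at T0, while Slfn1, Ms4a4c and Lair1 differed by 2.96, 2.38 and 0.90 at T0. Arhgap26 was higher in libraries labelled KO at T6 by 1.07 and at −0.75 at T32 (edgeR adjusted p = 0.0034 and 0.0096). The call of Htr2b was lost without the 4 WT libraries that had Y-linked transcripts.

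Interaction counts were compared with 100 groupings in which genotype labels were permuted within time points, the real one included. As many genes as the real 16, 11 and 61, and 72 in the joint test, came from 10, 4, 5 and 5 of them, with the highest of the others at 1769, 793, 458 and 192 genes. Shuffling time points separately can turn a constant genotype difference into interaction. These shares therefore cannot decide, and chance stays open. For the average over time points, only the real grouping of 100 gave as many as its 3527 genes. The highest other gave 208. That excludes chance only if libraries of different time points are independent, but WT ones probably share cultures. Where whole cultures, presumed from the order of the submitters' sample numbers, were kept together, 1 of 10 splits of 6 cultures gave as many, with 543 genes as the highest other, and 10 splits are too few for a share under 0.05. In simulated counts with an effect of each presumed culture, the average gave 576 false calls in edgeR. The comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. The real numbers and the highest of the other splits were 307 and 0 for KO against WT at T0 (1 of 10 as large; 239 to 1568 genes at an unadjusted p under 0.05 in the others) and 1009 and 0 at T32 (1 of 10; 106 to 542). They were 9332 and 0 for LPS in WT at T6 (1 of 10; 196 to 1854), 7320 and 0 at T32 (1 of 10; 126 to 842), and 9253 and 1989, 6903 and 0, and 6021 and 0 for LPS in libraries labelled KO (1 of 10 each). At T6, 3 of 10 splits gave as many as the real 47 genes. The split of KO replicates 1 and 3 with WT replicate 3 against the rest gave 1156 and that of KO replicates 1 and 3 with WT replicate 1 gave 370, which points to a structure of the T6 libraries other than genotype. Both leave libraries at the same place in the submitters' number order together, and such libraries of the 2 genotypes correlated at 0.5 to 0.85 at T6. With that order as a block these splits gave 2 and 0 genes. Among the 4 splits that part all 3 such pairs, 1 gave as many as the real 72 in the blocked fit, the real one itself, with 0 as the highest other in edgeR (254 to 671 genes at an unadjusted p under 0.05), and 4 splits are too few for a share under 0.05. In the T6 libraries alone with that block they gave 401 for the real split and 0 for the highest other (135 to 486 at an unadjusted p under 0.05).

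Interferon-response genes were higher in libraries labelled KO before LPS was added, and the list differed less at T6 (camera adjusted p of the change = 0.0065 with an estimated correlation), while by that test the change was not called at T16 and T32 (adjusted p = 0.13 and 0.14). Trace LPS would also raise cytokine genes, a list that was higher at T0 too (median 0.49). In genes induced at least 4-fold, the T0 excess was a median 0.63% of the rise to T6 for cytokines (quartiles 0.03 to 1.2). It was 10.57% for interferon genes (6.23 to 20.77). No trace dose was measured, so trace LPS stays open. A single T0 library did not carry the difference, since 32 of the 41 called genes remained called without WT replicate 3, the lowest number for any of them. Sex of the culture did not either, as 41 remained called with it as a covariate. A biological difference between the genotypes remains a hypothesis, as interferon from cultures or animals of another origin or strain was not tested.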

How the results depend on the processing

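The alternatives named above as added later were chosen after the data were seen. The other alternatives were set before. No named gene reversed its direction outside the joint interaction, which has none, and no list called by camera did in other camera fits. Yet scaling by library totals turned the sign of 20 of 160 list medians, none larger than 0.16. For named genes, 2416 of 2582 values under settings other than leaving out a library kept their direction and side of the threshold, 162 (from 65 of 199 pairs of gene and comparison) were no longer called and 4 became called; with single libraries left out, 4328 of 4577 kept theirs and 249 did not. For lists, 629 of 767 kept theirs, 114 were no longer called and 24 became called. Replicate numbers here follow accession order and pair nothing, but the submitters' sample numbers alternate between genotypes within each time point. As a hint from the data, not the design, libraries at the same place in that order deviated together (correlations across genes of deviations from group means) in 14 of 15 WT pairs of different time points, 12 of 18 KO-labelled pairs, and 0 of 3, 3 of 3, 0 of 2 and 2 of 3 pairs of genotypes at T0, T6, T16 and T32, judged at a correlation over 0.1. Among libraries of the other genotype at their time point, only 5 of 22 libraries correlated best with the one of their own number. For WT libraries the sex markers followed the order too: at each time point the 1 library with Y-linked transcripts was at place 3. WT libraries of different time points therefore probably share cultures or animals. With that order as a replicate block, calls were 359, 72, 1650, 1189 and 3968 between genotypes at T0, T6, T16 and T32 and in the average, and 19, 17 and 76 for the changes from T0; the T6 libraries alone gave 401 with this block. With it, MHC class I, inflammasome and NRF2 lists at T0 were called with an estimated correlation (adjusted p = 0.01, 0.037 and 0.037), as were the interferon, cytokine, MHC class I and inflammasome lists in the average (adjusted p = 0.047 each). With libraries of a presumed culture correlated (0.11; limma-voom) the average had 2594 and lost Cxcl9 and Acta2. Where a library left out leaves WT T16 with 1 sample, that sample is assumed to vary like the other groups. Unless a setting tests fewer genes or libraries by construction, the cause was not tested.

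Counts below are of called genes. A 2-fold threshold gave 21 at T6, 441 at T16, 565 at T32 and 422 for the average between genotypes, 6194, 3335 and 4108 for LPS in WT, and 3775 and 3288 for LPS in libraries labelled KO at T16 and T32. Scaling by library totals gave 122 at T6, 5596 for the average, and 37 and 19 for the changes from T0 to T6 and T16, and Stk40 in the average was at 0.15 (edgeR adjusted p = 0.075). Median-of-ratios scaling gave 7 and voom 8 for the change to T6. Without a filter the T6 and T16 numbers were 29 and 705, and with a filter at 5 CPM T32 gave 607, WT at T32 4619 and the change to T16 21.

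DESeq2 called 506, 269 and 2097 genes at T0, T6 and T16, 83, 219 and 233 for the changes from T0, and 404 in the joint test. A fit to the compared groups called 126, 0, 9 and 2688 at T0, T6, T16 and T32, and 0 and 3 for the changes to T6 and T16; the counts of 0 are from edgeR, with 722 and 592 genes at an unadjusted p under 0.05. Sex as a covariate gave 98 at T6 and 32, 25 and 92 for the changes. Without the 4 WT libraries with Y-linked transcripts there were 28 at T6, 117 at T16, 26 for the change to T32 and 22 in the joint test. Protein-coding genes alone gave 28 for the change to T32 and 47 in the joint test. With GC and length trends removed there were 165 at T6, 8, 26 and 138 for the changes and 134 in the joint test. Without both libraries led by Saa3 there were 25 at T6, 2401 at T16, and 5, 23 and 139 for the changes. With an estimated correlation the lists called were 1 at T0 and 0 at T6, T16, T32 and in the average (fry: 9, 0, 11, 15 and 20). With a 4-fold threshold the LPS-induced genes had a median genotype difference of 0.45 at T32.

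With single libraries left out, calls between genotypes ranged from 164 to 365 at T0, 15 to 73 at T6, 109 to 3537 at T16, 363 to 1242 at T32 and 2869 to 5061 for the average. LPS in WT ranged from 8207 to 9703, 4572 to 6221 and 5910 to 7913, and in libraries labelled KO from 8255 to 9664, 5349 to 7446 and 4425 to 6769. The changes from T0 ranged from 1 to 21, 4 to 1061 and 29 to 94, and the joint test from 25 to 639. Stk40 in the average ranged from 0.25 to 0.39. Depth limits low genes: in simulated counts, of genes changed 2-fold, 18% were recovered at T0 and 10% at T16 under a mean of 10 CPM, against 85% and 64% above it. T16 has 2 WT libraries.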

Other observations

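The ribosome gene lists, the tests of the parents of pseudogenes and of evenly spread genomic DNA, and the GC and length test of the T16 calls were chosen after the results were seen, as was the use of the sex covariate, a fit set before, to weigh those calls. The ribosome lists were written because such genes stood among the T16 calls, so their T16 values are not independent evidence. Of 50 ribosome biogenesis factors 21 fell at T16 and 0 rose (median −0.65, below 0 in 50), and of 20 aminoacyl-tRNA synthetases, the enzymes that charge tRNAs, 5 fell and 0 rose (median −0.36, below 0 in 20). Among 73 cytosolic ribosomal proteins 9 fell (median −0.71). Adjusted by Benjamini-Hochberg over these lists at every time point (12 tests), camera gave adjusted p = 4.2e-19, 3.6e-07 and 2.8e-11, and adjusted p = 0.11, 0.11 and 0.24 with an estimated correlation. Without WT T16 replicate 2 the medians were −0.66, −0.36 and −0.38 with fewer genes called, and after removal of GC and length trends they were −0.58, −0.37 and −0.4. At T32 the medians were −0.43, −0.21 and −0.55 with 3, 2 and 11 genes lower (camera adjusted p = 4.2e-10, 0.0012 and 1.4e-14, and 0.22 for each with an estimated correlation). The ribosomal proteins are uncertain there, as their genes may share reads with pseudogenes, which stood apart in WT.

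The T6 replicates 2 of both genotypes had 18.4 and 16.8 CPM on 1446 olfactory and vomeronasal receptor genes, against 40 to 56 CPM in the other T6 libraries.

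At T32, 212 lower genes were pseudogenes, and the pseudogene share of counts was 0.8% to 0.86% in KO-labelled libraries. WT had 1.02% to 1.07% at T32 but 0.7% to 0.85% at T0, T6 and T16, so WT at T32 stood apart. Lower expression of the protein-coding parents, or reads shared with them, may contribute and cannot be told apart from a change of the pseudogenes: over 1308 tested pseudogenes with a close relative the median was −0.42 against −0.08 for the relatives, with a median gap of −0.26 (quartiles −0.86 to 0.03) and a Spearman correlation of 0.43 across genes. Those without a relative had a median of −0.05 (120 genes). Genomic DNA was not settled by the WT to KO-labelled CPM ratio of those receptor genes, 0.78. Their RNA itself rose from at most 6.6 CPM at T0 to 56 at T6. Spread evenly over genes it does not account for the pattern, as these receptor genes had at most 0.0051 CPM per kb in a WT library while the lowest WT and the highest KO-labelled library were 0.13 CPM per kb apart in pseudogenes, and 174 of the 212 remained lower after removal of GC and length trends.

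The number of genes called at T16 rested on which WT library was used, with 109 genes against WT replicate 1 and 3537 against replicate 2. An effect of replicate 2 alone would leave no genotype signal against replicate 1, yet 90.7% of the 1009 genes called at T32 had the same sign there (97.2% of 790 without pseudogenes). Leaving out WT T32 replicate 1, which may share a culture with WT T16 replicate 1 by the number order, it was 91.2% of 568, but KO-labelled cultures may be shared too. Trends on GC content and length were stronger at T16 than at the other time points (Spearman −0.34 and 0.35 across genes), but 811 of the 1206 calls remained after their removal, and 925 remained with sex of the culture as a covariate. The share of calls owed to replicate 2 stays open, because with 2 WT libraries neither can be taken as typical, and a genotype difference that is larger at T16 remains a hypothesis that these data may hold but do not settle.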
